A study of Homo sapiens with 26 samples.

How the data were processed

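The samples were 26 Affymetrix Human Gene 1.0 ST arrays of NCCIT human embryonic carcinoma cells in 13 groups of 2. Per the labels' protocols, cells were grown in McCoy's medium with serum, transfected with siRNA by means of the PepMute reagent, and extracted with Trizol, and biotin-labelled cDNA was made from 250 ng of total RNA. The deposited values are log2 expression values per transcript cluster, 1 column per array. Partek is named without its role or version, per the submitters' processing notes. The log base is inferred from the range of the values (3.04 to 14.87), and the background correction, summarisation and normalization are not given in the sources used here. The quartiles of the 26 arrays are close but not identical, with medians from 6.28 to 6.33. The values look normalized between arrays, so an overall shift in transcript level would not be visible in them, and background signal compresses the differences of weakly expressed genes on arrays of this kind.

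The table holds 33297 rows and 26 columns, all of which match a sample. The platform's gene names gave 1 symbol for 19460 rows, several for 1754 and none for 12083. Rows with several symbols were not used for genes. Of the rows with 1 symbol, 19429 matched the RefSeq gene table of GRCh38.p14 by gene number, which was used for names only, and 0 were renamed. Where a symbol had more than 1 cluster (769 genes), the one with the highest mean was used, which left 18417 genes. No filter on low values was applied.

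Groups came from the sample titles. A linear model with 13 group means was fitted to all 26 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), which left 13 residual degrees of freedom, and p-values were adjusted by the method of Benjamini and Hochberg over the genes of a comparison, with 0.05 as the threshold. All p-values of genes come from this moderated test and are two-sided. The control was the mean of siNTC-1 and siNTC-2, since no label ties a depletion to either. Comparisons were the 11 depletions against control, 3 combinations against siDNMT1, the average effects of the 4 siRNAs, 5 interactions and siNTC-2 against siNTC-1. The average effect and interactions of DNMT1 were taken over the groups with and without siRNA against DNMT1, DNMT3A and DNMT3B, and the others over those of DNMT3A, DNMT3B and DNMT3L. An interaction is the effect of the first siRNA with the second minus that without it on the log2 scale, averaged over presence and absence of the remaining siRNA. Gene lists (24, fixed before the data were examined) were tested with camera of limma at a preset correlation between genes of 0.01, over 15 comparisons and 360 tests adjusted together. With that setting 59 tests were called, and 14 with an estimated correlation. Means are over all measured members of a list. Percent of control is computed from the log2 difference. The median log2 difference over all genes was between -0.02 and 0.02 in every comparison.

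The genes named for a depletion are the 5 largest rises and the 5 largest falls among those past the threshold with both arrays beyond all 4 control arrays. For an average effect they are among the 10 largest in each direction with the same sign in all 4 backgrounds, and for interactions and for the controls the 3 largest in each direction. The 4 targets are always named, and for a list up to 4 members with the smallest adjusted p are named, plus any needed to describe it. Genes named for comparisons within a set of arrays were chosen after their values were seen. Part of each set is printed, in order of size.

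Alternatives planned before the data were examined were a filter on the dimmest 40% of genes, quantile normalization, a trended and robust variance prior (for lists a trend only), array weights, the replicate number as a block, all clusters with 1 symbol, siNTC-1 or siNTC-2 alone as control, only the groups of a comparison, each array left out in turn, and for lists an estimated correlation and fry. A further alternative was added after the data were examined. The arrays fell into 2 sets along the first principal component of the rows without a symbol, 8 arrays of 4 groups and 18 arrays of 9 groups. No label names a batch, and the sets were inferred from the expression values, so they are not groups of the study. Taking the set as a block gives each depletion the control on its own side, with 2 control arrays where the planned result has 4, and is reported beside the planned result, not in its place. The split was the same along the first component of the genes. For a depletion against control the block gives the same differences as the planned comparison with siNTC-1 or siNTC-2 alone, but the p-values of lists are adjusted together with those of the other comparisons, so a call can differ. Comparisons of depletions within a set were added as well. For the average effects and interactions, every division of the 8 cells of the factorial into 4 and 4 (35, duplicates kept together) was counted with the same model. Families of small nucleolar RNA, histone, zinc finger and olfactory receptor genes were also chosen after the data were examined.

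The procedure was tested on simulated data for siDNMT1 against control with 18417 genes. It recovered 37 of 50 genes changed 1.25-fold, 48 of 50 changed 1.5-fold and 50 of 50 changed 2-fold, with 6 calls among 18217 unchanged genes. The simulated arrays had independent noise, equal controls and no array sets, so these rates need not hold for the real comparisons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures. The number of arrays limits precision, and p-values measure only the spread between duplicates of unstated origin.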

Results

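Transcript levels were measured on 26 Affymetrix Human Gene 1.0 ST arrays from NCCIT cells, a human embryonic carcinoma line that expresses pluripotency genes. The cells had been transfected with siRNA against DNA methyltransferases or with a control siRNA. DNMT1 copies methylation after DNA replication, DNMT3A and DNMT3B add methylation to unmethylated sites, and DNMT3L is a cofactor without catalytic activity of its own. There were 13 groups of 2 arrays each. Controls formed 2 of these groups, siNTC-1 and siNTC-2. The others received siRNA against DNMT1, DNMT3A, DNMT3B or DNMT3L alone, DNMT1 with DNMT3A, with DNMT3B or with both (siD1+3A, siD1+3B and siD1+3A+3B), or DNMT3 family members together (3A+3B, 3A+3L, 3B+3L and 3A+3B+3L). Duplicates correlated at 0.9973 to 0.9989 across genes. The labels do not say whether duplicates came from separate cultures, so the p-values measure only the spread between duplicate arrays, which may be technical. The number of arrays limits the precision of every value. Differences are on the log2 scale with their standard error, against the mean of both control groups unless another control is named, and changed genes are those that passed the threshold of limma after Benjamini-Hochberg adjustment among 18417 genes.

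The targeted transcripts were examined first. DNMT1 mRNA fell in all 4 groups that received its siRNA, to 39.3% of control in siDNMT1, 53.3% in siD1+3A, 47.5% in siD1+3B and 56.7% in siD1+3A+3B. DNMT3A mRNA fell in the 6 groups that received its siRNA, to between 62.3% and 73.0% of control. DNMT3B mRNA was at 56.0% of control after siRNA against DNMT3B alone (log2 difference -0.84 ± 0.05, n = 2 against 4, adjusted p = 2.0e-09). It was at 89.3% of control in 3A+3B+3L (log2 difference -0.16 ± 0.05, adjusted p = 0.0327). Against siNTC-2 alone, DNMT3B in 3A+3B+3L was at 99.4% of control (adjusted p = 0.951), so its depletion was not detectable with that control. DNMT3B in 3A+3B+3L was also not past the threshold when any of siNTC-1 replicate 2, either siNTC-2 array or either 3A+3B+3L array was left out (log2 difference -0.13, -0.16, -0.17, -0.13 and -0.19). DNMT3L mRNA was at 68.7% to 80.1% of control in its 4 groups. Its fall in 3A+3B+3L (log2 difference -0.32 ± 0.10, adjusted p = 0.0259) was not called without siNTC-1 replicate 2, siNTC-2 replicate 1 or either 3A+3B+3L array (-0.22, -0.32, -0.33 and -0.31). DNMT3L was also not called in 3B+3L (-0.39 ± 0.10, adjusted p = 0.00547) without 3B+3L replicate 1 (-0.31). DNMT3L mRNA was also lower in siDNMT1 (75.2% of control, adjusted p = 0.00407) and siDNMT3B (80.1%, adjusted p = 0.0182), which received no siRNA against it. With siNTC-1 alone as control the adjusted p in siDNMT3B was 0.0586.

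**Figure D1:**
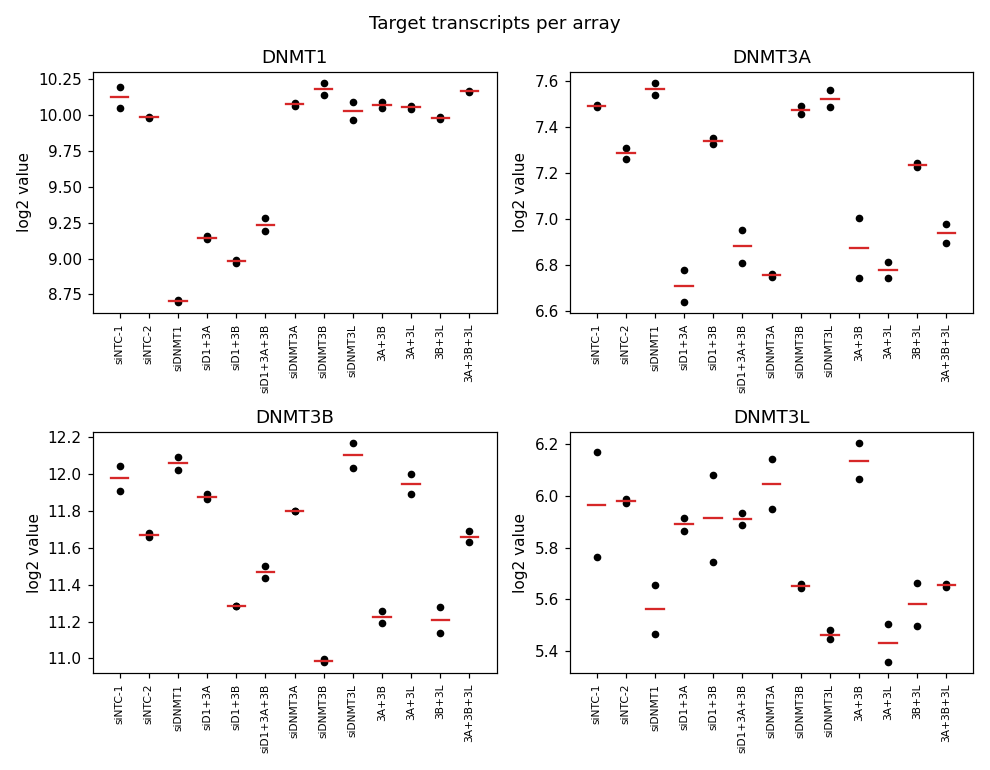
Log2 values of the DNMT1, DNMT3A, DNMT3B and DNMT3L transcripts (y axes) in the 13 groups (x axes). Points are single arrays and red bars are group means of 2 arrays, and the lowest DNMT1 values are those of the 4 groups that received DNMT1 siRNA.

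The control groups were then compared with each other. The largest rises in siNTC-2 were of TXNIP, a glucose-responsive inhibitor of thioredoxin, by 3.77 ± 0.07, CHAC1, a glutathione-degrading enzyme induced by ATF4, by 3.53 ± 0.12 and INHBE by 2.97 ± 0.13. The small nucleolar RNA SNORD14E was lower by 2.55 (difference -2.55 ± 0.13), as were AAMP (-2.14 ± 0.07) and SNORD59B (-1.72 ± 0.10). In all, 8234 genes differed between siNTC-2 and siNTC-1, 4451 higher and 3783 lower, and 1633 of them differed by at least 1.5-fold. Of 23 genes of the integrated stress and unfolded protein response, 19 were higher and 2 lower in siNTC-2 (mean 1.11, camera adjusted p = 1.3e-12, and adjusted p = 0.00967 with an estimated correlation). Cholesterol synthesis genes were lower (11 of 16, mean -0.44, adjusted p = 2.1e-06, and adjusted p = 0.161 with an estimated correlation), and so were DNA replication genes (20 of 28, mean -0.33, adjusted p = 2.1e-06, and adjusted p = 0.154 with an estimated correlation).

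The depletion groups divided in the same way. The first principal component held 49.5% of the variance of the genes and placed siDNMT1, siDNMT3B and siDNMT3L beside siNTC-1, and the other 8 depletions on the side of siNTC-2. The same split appeared in the 12083 rows without a gene symbol. Each comparison is therefore also given against the control group on its own side, called the nearer control: siNTC-1 for siDNMT1, siDNMT3B and siDNMT3L, and siNTC-2 for the other depletions. The nearer control was chosen after the data were examined, and it has 2 arrays where both controls have 4. With it fewer genes changed in each of the 11 depletions. More changed by at least 1.5-fold, however, in siD1+3A (386 against 240), siD1+3B (486 against 305), siD1+3A+3B (262 against 170), 3A+3L (384 against 225) and 3A+3B+3L (424 against 208). Of the genes called with both readings, 55 to 149 per depletion had opposite directions.

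**Figure D2:**
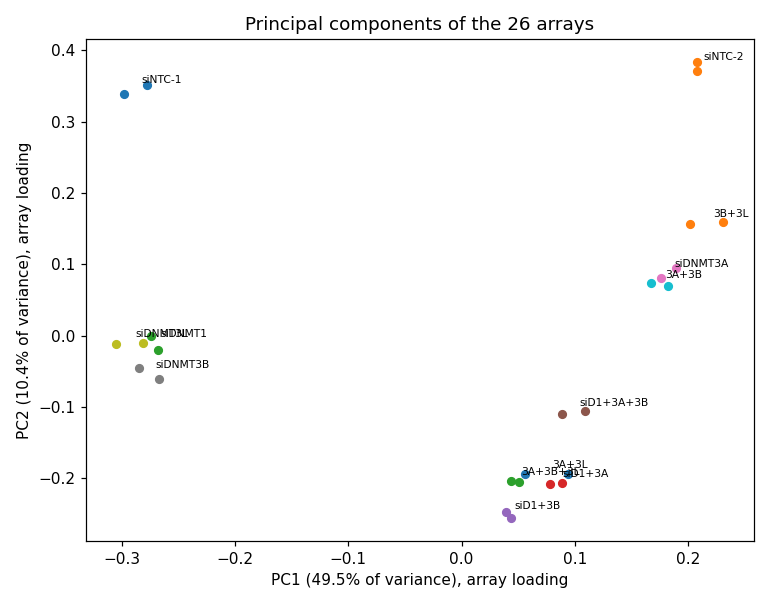
Loadings of the 26 arrays on the first (x axis, 49.5% of the variance) and second (y axis, 10.4%) principal components of 18417 genes. Each point is an array and points of a group share a colour and label, and the 8 arrays of siNTC-1, siDNMT1, siDNMT3B and siDNMT3L lie at negative values of the first component.

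Depletion of DNMT1 alone raised the histone gene H3C11 by 2.25 ± 0.10, the extracellular matrix gene TNC by 2.11 ± 0.05 and DUSP6, a phosphatase of ERK, by 2.04 ± 0.12 (n = 2 against 4 arrays, as in all comparisons with control). Against the nearer control these differences were 2.67, 1.82 and 1.94. Values of histone genes are uncertain because near-identical copies can share probes. GUCY2C, an intestinal guanylate cyclase, rose by 1.75 ± 0.08 and the linker histone gene H1-5 by 1.68 ± 0.11. The largest falls were those of CHAC1 (-2.46 ± 0.11), PCK2 (-1.96 ± 0.07), INHBE (-1.86 ± 0.11), HHIP, an inhibitor of hedgehog signalling (-1.83 ± 0.06), and TRIB3 (-1.73 ± 0.10). Against the nearer control they were -0.70, -0.62, -0.38, -1.41 and -0.41. Germline and meiosis genes rose: 14 of 34 were higher and none lower (16 and 0 adjusted over the list alone), with a mean of 0.22 (adjusted p = 0.000121, and adjusted p = 0.0398 with an estimated correlation). Among them were TDRD1 (0.96 ± 0.07) and MAEL (1.24 ± 0.10), both of the piRNA pathway, and HORMAD1 (1.01 ± 0.14), a protein of meiotic chromosomes. Metallothioneins rose as well, 6 of 10 members with a mean of 0.43 (7 adjusted over the list alone, adjusted p = 4.8e-06, and adjusted p = 0.0149 with an estimated correlation), led by MT1X (0.90 ± 0.06) and MT1G (0.70 ± 0.04). Protocadherin beta genes were lower, 10 of 16 with a mean of -0.29 (10 adjusted over the list alone, adjusted p = 0.00276, and adjusted p = 0.127 with an estimated correlation), for example PCDHB5 (-0.31 ± 0.05) and PCDHB12 (-0.57 ± 0.10). The stress-response list was lower in 20 of 23 members (20 adjusted over the list alone) with a mean of -0.83 (adjusted p = 1.6e-15, and adjusted p = 0.0149 with an estimated correlation), with DDIT3 at -1.58 ± 0.05 and PSAT1 at -1.23 ± 0.04. Its mean was -0.28 against the nearer control (adjusted p = 2.4e-06, and adjusted p = 0.0757 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 16 members and none fell (14 and 0 adjusted over the list alone, mean 0.35, adjusted p = 3.4e-09, and adjusted p = 0.102 with an estimated correlation), such as HMGCS1 (0.75 ± 0.04) and INSIG1 (0.86 ± 0.07), and the mean against the nearer control was 0.13. Pluripotency genes were higher in 10 of 23 members and lower in 3 (10 and 3 adjusted over the list alone, mean 0.12, adjusted p = 0.00833, and adjusted p = 0.127 with an estimated correlation). DDIT3, PSAT1, MT1X, HMGCS1 and INSIG1 were at -0.77, -0.65, 0.59, 0.20 and 0.405 against the nearer control. Without the 40% dimmest genes the germline list (5 of 34 members left, mean 0.26, adjusted p = 0.126) and the protocadherin beta list (7 of 16 left, mean -0.34, adjusted p = 0.0545) were not called in siDNMT1. With siNTC-2 alone the protocadherin beta list (-0.29, adjusted p = 0.0817) and the pluripotency list (0.10, adjusted p = 0.192) were not called. In all, 2364 genes rose and 3281 fell, 5645 together, of which 488 changed by at least 1.5-fold. Against the nearer control 3653 genes changed, and 2310 were called in the same direction with both controls.

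**Figure D3:**
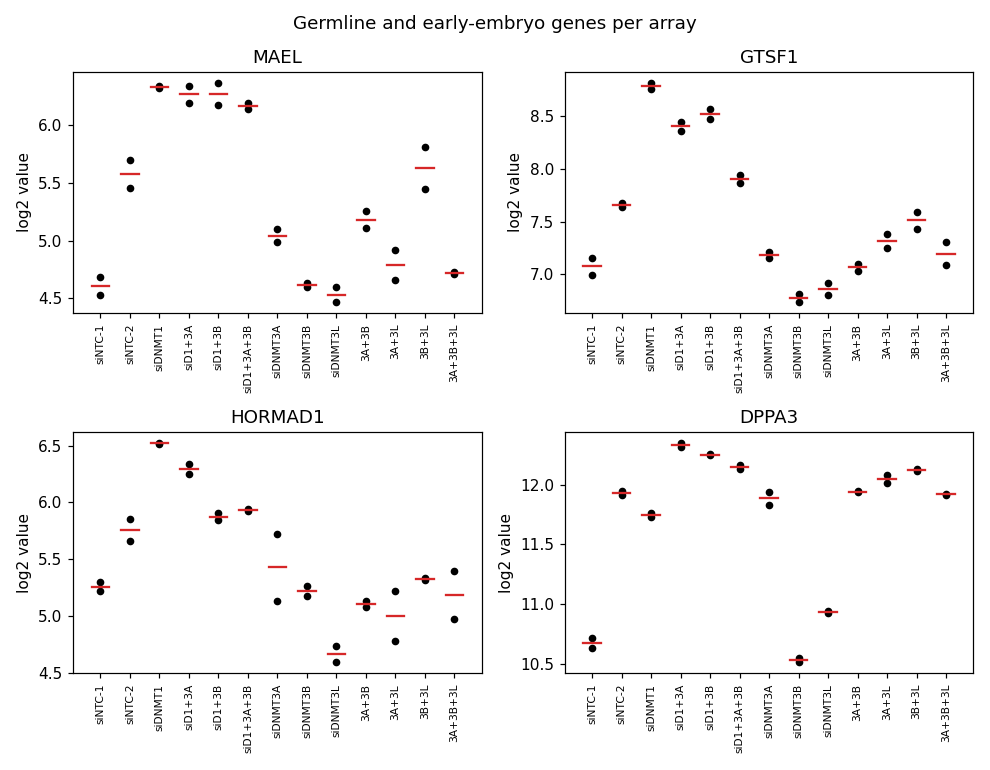
Log2 values of MAEL, GTSF1, HORMAD1 and DPPA3 (y axes) in the 13 groups (x axes), with points for arrays and red bars for means of 2 arrays. MAEL was higher by 1.24 in siDNMT1 than in the mean of the controls.

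Depletion of DNMT3A alone raised RPPH1, the RNA of ribonuclease P (1.54 ± 0.07), the transcription factor gene NFE2L3 (1.44 ± 0.08), ACTN3, a muscle actinin (1.39 ± 0.08), the basement membrane gene NID1 (1.36 ± 0.07) and GNG4 (1.26 ± 0.06). AAMP (-1.48 ± 0.06), SHISA3 (-1.40 ± 0.12), RPL22L1 (-1.18 ± 0.07), THBS2 (-1.10 ± 0.06) and TENM2 (-1.01 ± 0.08) fell. Against the nearer control SHISA3 was at -1.43 and TENM2 at -1.25, while RPPH1 was at 0.85, NFE2L3 at 0.62, NID1 at 0.78, GNG4 at 0.73, AAMP at -0.41, RPL22L1 at -0.66 and THBS2 at -0.58. Stress-response genes were higher in 17 of 23 members (18 adjusted over the list alone) with a mean of 0.33 (adjusted p = 1.7e-07, and adjusted p = 0.0633 with an estimated correlation). Their direction turned against the nearer control, where the mean was -0.23 (adjusted p = 6.1e-06, and adjusted p = 0.0798 with an estimated correlation). DDIT4, for example, was at 1.13 ± 0.07 and CHAC1 at 1.39 ± 0.10, against -0.19 and -0.38 with the nearer control. DNA replication genes were lower in 17 of 28 members and higher in 2 (19 and 2 adjusted over the list alone, mean -0.14, adjusted p = 4.0e-05, and adjusted p = 0.185 with an estimated correlation), for example MCM7 (-0.43 ± 0.04). The replication mean was 0.02 against the nearer control (adjusted p = 0.725), and MCM7 was at 0.10. In all, 3176 genes rose and 2251 fell, 5427 together. Against the nearer control 2911 changed, 1698 of them in the same direction as with both controls. Without siDNMT3A replicate 1 the count against both controls was 3142.

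Depletion of DNMT3B alone raised SHC3, an adaptor of receptor signalling (2.00 ± 0.08), DUSP6 (1.87 ± 0.12), DHRS2 (1.69 ± 0.07), the surface glycoprotein gene THY1 (1.48 ± 0.06) and AK4 (1.44 ± 0.06). MAP2, a neuronal microtubule protein, was at -1.96 ± 0.08 and TFAP2A, a transcription factor of trophoblast and neural crest, at -1.83 ± 0.05. Both also fell against the nearer control, to -2.33 and -1.68. DDIT4 (-1.81 ± 0.07), the amino acid transporter gene SLC7A5 (-1.66 ± 0.06) and STK32A (-1.62 ± 0.04) fell, and were at -0.49, -0.61 and -0.58 against the nearer control. Of the hypoxia and glycolysis genes, 11 of 18 were higher and 4 lower (11 and 4 adjusted over the list alone, mean 0.15, adjusted p = 0.0165, and adjusted p = 0.573 with an estimated correlation), including LDHA (0.67 ± 0.04) and SLC2A1 (0.64 ± 0.06). SLC2A1 was at 0.06 against the nearer control. Stress-response genes were lower in 18 of 23 members (19 adjusted over the list alone, mean -0.69, adjusted p = 8.0e-12, and adjusted p = 0.0249 with an estimated correlation), with DDIT3 at -1.47 ± 0.05. Its mean against the nearer control was -0.13 (adjusted p = 0.0261, and adjusted p = 0.430 with an estimated correlation). Cholesterol synthesis genes were higher in 12 of 16 members and lower in 2 (13 and 2 adjusted over the list alone, mean 0.33, adjusted p = 3.5e-06, and adjusted p = 0.172 with an estimated correlation), with SQLE at 0.71 ± 0.05. The cholesterol list was not past the threshold against the nearer control (mean 0.11, adjusted p = 0.104). Metallothioneins (5 of 10 higher, 5 adjusted over the list alone, mean 0.21, adjusted p = 0.0278, and adjusted p = 0.127 with an estimated correlation) were called as well. So were mitosis genes (14 of 24 higher and 3 lower, 15 and 3 adjusted over the list alone, mean 0.12, adjusted p = 0.00299, and adjusted p = 0.231 with an estimated correlation), but not against the nearer control (adjusted p = 0.0796). Metallothioneins were not called in siDNMT3B without siDNMT3B replicate 2 (mean 0.20, adjusted p = 0.0517), after quantile normalization (0.20, adjusted p = 0.0515) or without dim genes (0.24, adjusted p = 0.0902). The hypoxia list was not called without dim genes (0.14, adjusted p = 0.0636). With siNTC-2 alone neither the metallothioneins (0.26, adjusted p = 0.118) nor the hypoxia list (0.11, adjusted p = 0.12) was called. DDIT3 and SQLE were at -0.66 and 0.24 against the nearer control. Ribosomal protein genes, a list for RNA quality, were not called against both controls (10 of 25 lower and 1 higher, 10 and 1 adjusted over the list alone, mean -0.11, adjusted p = 0.0626). They were lower against the nearer control (11 of 25, 12 and 1 higher adjusted over the list alone, mean -0.14, adjusted p = 0.00200, and adjusted p = 0.451 with an estimated correlation), after quantile normalization (adjusted p = 0.0161), with a trend in the variance prior (0.0155) and without siDNMT3B replicate 2 (0.0380). In all, 2921 genes rose and 3638 fell, 6559 together, and 4465 changed against the nearer control.

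Depletion of DNMT3L alone raised the vault RNA VTRNA1-1 (1.88 ± 0.12), GUCY2C (1.84 ± 0.08), DUSP6 (1.76 ± 0.12), TNC (1.69 ± 0.05) and ANXA1, an annexin (1.57 ± 0.06). CHAC1 (-2.11 ± 0.11), INHBE (-1.82 ± 0.11), HHIP (-1.81 ± 0.06), STK32A (-1.73 ± 0.04) and PRTG (-1.68 ± 0.07) fell. The falls of CHAC1 and INHBE were not past the threshold against the nearer control (-0.35, adjusted p = 0.0542, and -0.33, adjusted p = 0.072), whereas HHIP was at -1.39, STK32A at -0.68 and PRTG at -1.70. VTRNA1-1 was at 1.16 against that control. Metallothioneins rose (7 of 10, 7 adjusted over the list alone, mean 0.36, adjusted p = 0.000164, and adjusted p = 0.0249 with an estimated correlation), with MT1X at 1.20 ± 0.06 and MT1E at 0.66 ± 0.07. Pluripotency genes were higher in 10 of 23 members and lower in 4 (11 and 5 adjusted over the list alone, mean 0.13, adjusted p = 0.0389, and adjusted p = 0.222 with an estimated correlation), with GDF3 at 1.01 ± 0.04 and L1TD1 at 0.51 ± 0.04. The pluripotency list was not called without siNTC-1 replicate 1 (0.13, adjusted p = 0.0545), without siDNMT3L replicate 1 (0.10, adjusted p = 0.109), after quantile normalization (0.11, adjusted p = 0.0741), without dim genes (0.15, adjusted p = 0.0546) when only the groups compared were fitted (adjusted p = 0.0778) or with siNTC-2 alone (0.10, adjusted p = 0.233). GDF3 and SLC7A11 were at 0.48 and -0.33 against the nearer control. Stress-response genes were lower in 18 of 23 members (18 adjusted over the list alone, mean -0.67, adjusted p = 3.7e-11, and adjusted p = 0.0249 with an estimated correlation), with SLC7A11, a cystine transporter, at -0.97 ± 0.04. The mean against the nearer control was -0.11 (adjusted p = 0.00823, and adjusted p = 0.359 with an estimated correlation). Cholesterol synthesis genes were higher in 9 of 16 members (10 adjusted over the list alone, mean 0.24, adjusted p = 7.5e-05, and adjusted p = 0.243 with an estimated correlation), and the mean against the nearer control was 0.02 (adjusted p = 0.713). In all, 2662 genes rose and 3446 fell, 6108 together, and 3532 changed against the nearer control.

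Next, DNMT1 was depleted together with the DNMT3 enzymes. H3C11 rose in siD1+3A (2.29 ± 0.10), siD1+3B (1.83 ± 0.10) and siD1+3A+3B (1.37 ± 0.10), and the histone gene H2AC14 rose by 1.90 ± 0.23, 1.48 ± 0.23 and 1.45 ± 0.23. H2AC14 was at 1.17 and 0.755 in siD1+3A and siD1+3B against the nearer control, and in siD1+3A+3B it did not pass the threshold (0.72, adjusted p = 0.0681). SHISA3 fell in siD1+3A (-1.68 ± 0.12), siD1+3B (-1.38 ± 0.12) and siD1+3A+3B (-1.54 ± 0.12), and HHIP fell in siD1+3A (-1.27 ± 0.06) and siD1+3B (-1.62 ± 0.06). In siD1+3A the stress-response list was lower (mean -0.22, 11 of 23 lower, 12 adjusted over the list alone, adjusted p = 0.000441, and adjusted p = 0.200 with an estimated correlation). So it was in siD1+3B (mean -0.38, 15 of 23 lower, 16 adjusted over the list alone, adjusted p = 1.6e-08, and adjusted p = 0.0475 with an estimated correlation). SLC7A11 was at -0.66 ± 0.04 and ALDH1L2 at -0.97 ± 0.06 in siD1+3A, and DDIT3 was at -0.91 ± 0.05 in siD1+3B. They were at -1.30, -2.01 and -1.73 against the nearer control. Against siNTC-2 the list's means were -0.78 in siD1+3A and -0.94 in siD1+3B, and against siNTC-1 they were 0.34 and 0.18, so its direction depended on the control. Cholesterol synthesis genes were higher in siD1+3B (10 of 16, 10 adjusted over the list alone, mean 0.30, adjusted p = 2.6e-06, and adjusted p = 0.171 with an estimated correlation), with HMGCS1 at 0.67 ± 0.04. They were higher in siD1+3A (8 of 16, 8 adjusted over the list alone, mean 0.23, adjusted p = 0.000223, and adjusted p = 0.291 with an estimated correlation). In siD1+3A+3B they were higher as well (7 of 16 and 1 lower, 7 and 1 adjusted over the list alone, mean 0.19, adjusted p = 0.000459, and adjusted p = 0.333 with an estimated correlation). The cholesterol means were 0.45, 0.52 and 0.41 in siD1+3A, siD1+3B and siD1+3A+3B against the nearer control, with HMGCS1 at 1.21 in siD1+3B. Against siNTC-1 they were 0.01, 0.08 and -0.03, and none of the 3 was called (adjusted p = 0.944, 0.817 and 0.817). DNA replication genes were lower in siD1+3A, siD1+3B and siD1+3A+3B (means -0.09, -0.09 and -0.15, with 11, 13 and 14 of 28 members lower, 12, 16 and 16 adjusted over the list alone, adjusted p = 0.00681, 0.0120 and 7.0e-06, and adjusted p = 0.447, 0.495 and 0.148 with an estimated correlation). With siNTC-2 those means were 0.07, 0.07 and 0.01 and not called (adjusted p = 0.235, 0.253 and 0.899). Metallothioneins were higher in siD1+3A and siD1+3A+3B (4 of 10 members in each, 4 adjusted over the list alone, means 0.18 and 0.15, adjusted p = 0.0221 and 0.0204, and adjusted p = 0.127 in both with an estimated correlation). Mitosis genes were higher in siD1+3A (9 of 24, 9 adjusted over the list alone, mean 0.11, adjusted p = 0.00265, and adjusted p = 0.228 with an estimated correlation). Pluripotency genes were higher in siD1+3B (11 of 23 and 1 lower, 11 and 1 adjusted over the list alone, mean 0.14, adjusted p = 0.0221, and adjusted p = 0.171 with an estimated correlation), DPPA3 at 0.95 ± 0.04 among them. That call was lost against the nearer control (0.11, adjusted p = 0.0663), where DPPA3 was at 0.32, and against siNTC-1 (0.16, adjusted p = 0.481). Respiratory chain genes, a list for RNA quality, were also higher in siD1+3B (13 of 24, 14 adjusted over the list alone, mean 0.11, adjusted p = 0.0307, and adjusted p = 0.679 with an estimated correlation). Metallothioneins in siD1+3A were not called without siD1+3A replicate 1 (0.16, adjusted p = 0.0795), and respiratory chain genes in siD1+3B not without siD1+3B replicate 1 (0.10, adjusted p = 0.0793) or after quantile normalization (0.12, adjusted p = 0.053). Against siNTC-1 the mitosis list in siD1+3A (0.06, adjusted p = 0.669), the metallothioneins in siD1+3A and siD1+3A+3B (0.135 and 0.10, adjusted p = 0.284 and 0.411) and the respiratory chain list in siD1+3B (0.002, adjusted p = 0.944) were not called. Without dim genes the metallothionein (adjusted p = 0.0677 and 0.0700), mitosis (0.0545) and respiratory chain (0.126) lists of these groups were not called, nor with only the groups compared the pluripotency (0.0659) and respiratory chain (0.0662) lists. The counts of changed genes were 5042 in siD1+3A, 5081 in siD1+3B and 4500 in siD1+3A+3B, and 4205, 4599 and 3424 against the nearer control. Without replicate 1 or 2 of the depletion, the counts against both controls were 3163 and 2962 in siD1+3A, 3259 and 3290 in siD1+3B and 2723 and 2838 in siD1+3A+3B. Against siDNMT1, 6400 genes differed in siD1+3A, 5892 in siD1+3B and 6463 in siD1+3A+3B. Those groups lie on the other side of the first component from siDNMT1, and the counts were 3298, 3228 and 2908 when the difference between the controls was taken out. Of the genes called both ways, 1108, 836 and 905 then had the same direction and 741, 799 and 734 the opposite one.

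**Figure D4:**
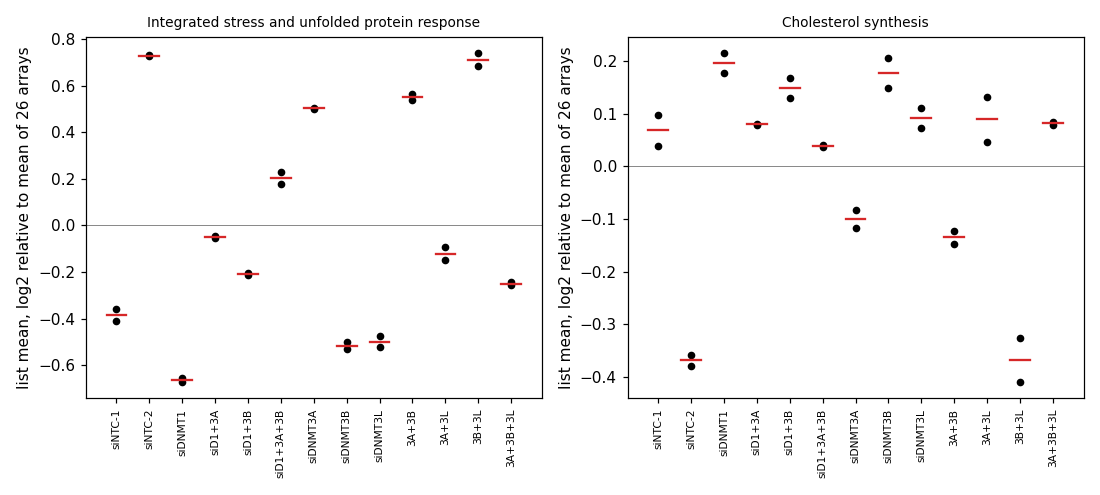
Mean log2 value per array of 23 integrated stress and unfolded protein response genes (left) and 16 cholesterol synthesis genes (right), relative to the mean of the 26 arrays (y axes), in the 13 groups (x axes). Points are arrays and red bars are means of 2 arrays, and the stress-response mean is 1.11 higher in siNTC-2 than in siNTC-1.

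The combinations of DNMT3 siRNAs shared low levels of SHISA3, at -1.33 ± 0.12 in 3A+3B, -2.01 ± 0.12 in 3A+3L, -1.07 ± 0.12 in 3B+3L and -2.02 ± 0.12 in 3A+3B+3L. Its values against the nearer control differed from these by little (-1.35, -2.03, -1.10 and -2.04). HHIP fell in 3A+3L (-1.52 ± 0.06) and 3A+3B+3L (-1.66 ± 0.06). In 3B+3L the largest falls were in ACTG2 (-1.65 ± 0.07), MAP2 (-1.58 ± 0.08) and AAMP (-1.28 ± 0.06), of which AAMP did not pass the threshold against the nearer control (-0.21, adjusted p = 0.0741). The largest rises in 3B+3L were in TXNIP (2.10 ± 0.06), PCK2 (1.67 ± 0.07) and ARRDC4 (1.62 ± 0.09), which were at 0.21, 0.34 and 0.42 against the nearer control, and that of TXNIP was then not past the threshold (adjusted p = 0.0721). Other rises included NFE2L3 in 3A+3B (1.34 ± 0.08) and 3A+3L (1.32 ± 0.08) and RPPH1 in 3A+3B+3L (1.59 ± 0.07), which were at 0.53, 0.51 and 0.90 against the nearer control. Stress-response genes were higher in 3A+3B (mean 0.38, 15 of 23 higher, 15 adjusted over the list alone, adjusted p = 5.6e-09, and adjusted p = 0.0417 with an estimated correlation). They were also higher in 3B+3L (mean 0.54, 18 of 23, 19 adjusted over the list alone, adjusted p = 5.6e-11, and adjusted p = 0.0249 with an estimated correlation). The list was lower in 3A+3L (mean -0.29, 15 of 23, 15 adjusted over the list alone, adjusted p = 2.0e-05, and adjusted p = 0.127 with an estimated correlation). In 3A+3B+3L it was lower too (mean -0.42, 17 of 23, 17 adjusted over the list alone, adjusted p = 3.4e-09, and adjusted p = 0.0398 with an estimated correlation). Against siNTC-2 the means were -0.18, -0.02, -0.85 and -0.98 in the order 3A+3B, 3B+3L, 3A+3L and 3A+3B+3L, and that in 3B+3L was not called (adjusted p = 0.708). Against siNTC-1 the means in 3A+3L and 3A+3B+3L turned to 0.26 and 0.13 (adjusted p = 0.0136 and 0.392). In 3A+3B+3L, SLC7A11 was at -0.75 ± 0.04 and STC2 at -1.17 ± 0.06, and at -1.39 and -1.95 against the nearer control. Cholesterol synthesis genes were higher in 3A+3L and 3A+3B+3L (10 of 16 members in each, 10 adjusted over the list alone, means 0.24 and 0.23, adjusted p = 6.5e-05 and 7.5e-05, and adjusted p = 0.243 in both with an estimated correlation). Against siNTC-1 the means were 0.02 and 0.01 and neither was called (adjusted p = 0.981 and 0.971), and against siNTC-2 they were 0.46 and 0.45. They were lower in 3B+3L (11 of 16, 11 adjusted over the list alone, mean -0.22, adjusted p = 7.1e-05, and adjusted p = 0.243 with an estimated correlation), where the mean against siNTC-2 was 0.001. DNA replication genes were lower in 3A+3B (19 of 28, 22 adjusted over the list alone, mean -0.18, adjusted p = 9.1e-07, and adjusted p = 0.127 with an estimated correlation). They were also lower in 3A+3L (12 of 28, 13 adjusted over the list alone, mean -0.11, adjusted p = 0.0118, and adjusted p = 0.495 with an estimated correlation). The largest number of members was lower in 3B+3L (23 of 28, 25 adjusted over the list alone, mean -0.27, adjusted p = 2.4e-09, and adjusted p = 0.0630 with an estimated correlation). Against siNTC-2 the replication means were -0.02, 0.06 and -0.10 in the same order, and the first 2 were not called (adjusted p = 0.913 and 0.233). Pluripotency genes were higher in 3A+3L (9 of 23 and 1 lower, 10 and 2 adjusted over the list alone, mean 0.13, adjusted p = 0.00898, and adjusted p = 0.127 with an estimated correlation). So they were in 3A+3B+3L (10 of 23, 11 and 1 adjusted over the list alone, mean 0.14, adjusted p = 0.00130, and adjusted p = 0.0796 with an estimated correlation). The call in 3A+3L was lost against the nearer control (0.11, adjusted p = 0.0651), and both were lost against siNTC-1 (adjusted p = 0.420 and 0.241). Mitosis genes were higher in 3A+3L (10 of 24 and 1 lower, 10 and 1 adjusted over the list alone, mean 0.10, adjusted p = 0.00532, and adjusted p = 0.243 with an estimated correlation). X-linked cancer-testis genes were lower in 3A+3L (3 of 27, 2 adjusted over the list alone, mean -0.11, adjusted p = 0.0496, and adjusted p = 0.128 with an estimated correlation). They were lower in 3B+3L too (6 of 27, 5 adjusted over the list alone, mean -0.13, adjusted p = 0.0314, and adjusted p = 0.127 with an estimated correlation). Neither was called against siNTC-2 (adjusted p = 0.638 and 0.216) or after quantile normalization (means -0.06 and -0.07, adjusted p = 0.165 and 0.102), with a trend in the variance prior (0.0794 and 0.0525), or in 3A+3L with array weights (0.0503). The call in 3A+3L was also lost without siNTC-1 replicate 1 (-0.11), siNTC-1 replicate 2 (-0.12), siNTC-2 replicate 2 (-0.10) or 3A+3L replicate 2 (-0.11). That in 3B+3L was lost without siNTC-2 replicate 2 (-0.12) or 3B+3L replicate 1 (-0.10). It was also lost against siNTC-1 (-0.19, adjusted p = 0.0618). The mitosis list in 3A+3L was not called without dim genes (adjusted p = 0.0681) or against siNTC-1 (0.04, adjusted p = 0.770). The counts of changed genes were 4925 in 3A+3B, 5043 in 3A+3L, 6041 in 3B+3L and 4619 in 3A+3B+3L, and 2319, 4126, 1860 and 4297 against the nearer control. Without replicate 1 or 2 of the depletion the counts against both controls were 3044 and 2917 in 3A+3B and 2673 and 2707 in 3A+3B+3L, and 3338 in 3A+3L without its replicate 2.

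The effect of each siRNA was also averaged over the 4 backgrounds in which it was given or left out. With DNMT1 siRNA, H3C11 was higher by 1.96 ± 0.06, GTSF1 by 1.31 ± 0.04, MAEL by 1.27 ± 0.05, the linker histone gene H1-5 by 1.25 ± 0.06 and HORMAD1 by 0.84 ± 0.08. The same sign in all 4 backgrounds was a condition for naming a gene here. GTSF1 and MAEL act in piRNA silencing of transposons in germ cells. HHIP (-1.21 ± 0.04), DNMT1 (-1.08 ± 0.03), STC2 (-0.76 ± 0.04), NIBAN1 (-0.71 ± 0.04) and BSG (-0.70 ± 0.03) were lower. Germline genes rose in 15 of 34 members and none fell (17 and 0 adjusted over the list alone), with a mean of 0.16 (adjusted p = 8.0e-07, and adjusted p = 0.0170 with an estimated correlation). In siD1+3A, siD1+3B and siD1+3A+3B the list was not called (means 0.09, 0.09 and 0.04, adjusted p = 0.462, 0.358 and 0.755). Stress-response genes were lower (18 of 23, 18 adjusted over the list alone, mean -0.36, adjusted p = 2.6e-16, and adjusted p = 0.0149 with an estimated correlation), with DDIT3 at -0.68 ± 0.03 and SLC7A11 at -0.51 ± 0.02. Metallothioneins rose (6 of 10, 7 adjusted over the list alone, mean 0.13, adjusted p = 0.000708, and adjusted p = 0.0398 with an estimated correlation). Cholesterol synthesis genes rose too (11 of 16, 14 adjusted over the list alone, mean 0.17, adjusted p = 5.6e-09, and adjusted p = 0.106 with an estimated correlation). Protocadherin beta genes were lower (4 of 16, 4 adjusted over the list alone, mean -0.12, adjusted p = 0.00922, and adjusted p = 0.171 with an estimated correlation). Without dim genes the average-effect calls of the germline list (5 of 34 members left, mean 0.16, adjusted p = 0.0902) and the protocadherin beta list (mean -0.13, adjusted p = 0.126) were lost. Of the lists for RNA quality, ribosomal protein genes (8 of 25 higher, 9 adjusted over the list alone, mean 0.07, adjusted p = 0.000324, and adjusted p = 0.447 with an estimated correlation) moved with these groups. Respiratory chain genes did as well (13 of 24 higher and 1 lower, 15 and 1 adjusted over the list alone, mean 0.08, adjusted p = 0.000459, and adjusted p = 0.445 with an estimated correlation), but not with siNTC-1 alone (0.05, adjusted p = 0.134). In all, 4041 genes changed, 37 of them by at least 1.5-fold, and 3332 were called in the same direction with the nearer controls.

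With DNMT3A siRNA the largest average rises were H2AC15 (1.27 ± 0.04), RPPH1 (1.25 ± 0.04), SAT1 (1.14 ± 0.03), ACTN3 (0.99 ± 0.04) and STMN2 (0.91 ± 0.02), and the largest falls SHISA3 (-0.93 ± 0.07), RPL22L1 (-0.74 ± 0.04), S100A13 (-0.74 ± 0.03), HAP1 (-0.74 ± 0.06) and SPINK1 (-0.73 ± 0.04). With the nearer controls H2AC15 was at 0.05 (adjusted p = 0.708), while STMN2 was at 0.86 and SHISA3 at -0.97. In all, 8332 genes changed. All groups with DNMT3A siRNA lay on the side of siNTC-2, whereas siNTC-1, siDNMT3B and siDNMT3L did not. With the nearer controls 4099 genes were called, and of the genes called both ways 1681 had the same direction and 1011 the opposite one. RPL22L1 and S100A13 were no longer called (adjusted p = 0.334 and 0.127), and RPPH1, SAT1, ACTN3 and SPINK1 were at 0.39, 0.40, 0.51 and -0.39. Stress-response genes were higher (18 of 23, 18 adjusted over the list alone, mean 0.20, adjusted p = 9.3e-05, and adjusted p = 0.151 with an estimated correlation). They turned with the nearer controls (mean -0.49, adjusted p = 1.5e-13, and adjusted p = 0.0105 with an estimated correlation) and were not called with siNTC-2 alone (0.06, adjusted p = 0.310).

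With DNMT3B siRNA, L1CAM, a neural adhesion molecule, was higher by 0.59 ± 0.05, HAP1 by 0.53 ± 0.06, KIF1A by 0.48 ± 0.04, DSP by 0.47 ± 0.04 and ARHGEF6 by 0.46 ± 0.05. MAP2 (-0.72 ± 0.04), ACTG2 (-0.71 ± 0.04), DNMT3B (-0.65 ± 0.03), CDH9 (-0.57 ± 0.06) and HAPLN1 (-0.54 ± 0.05) were lower. With the nearer controls these 10 were at 0.48, 0.465, 0.33, 0.38, 0.32, -0.63, -0.61, -0.61, -0.49 and -0.40. On average stress-response genes were higher (12 of 23 and 1 lower, 12 and 2 adjusted over the list alone, mean 0.11, adjusted p = 1.4e-05, and adjusted p = 0.127 with an estimated correlation). DNA replication genes were lower (12 of 28 and 1 higher, 15 and 3 adjusted over the list alone, mean -0.06, adjusted p = 3.5e-05, and adjusted p = 0.182 with an estimated correlation). Neither list was called with the nearer controls (adjusted p = 0.276 and 0.204). Cholesterol synthesis genes (3 of 16 lower, 4 adjusted over the list alone, mean -0.04, adjusted p = 0.0350, and adjusted p = 0.668 with an estimated correlation) were lower by small amounts. So were ribosomal protein genes (4 of 25 lower and 1 higher, 5 and 1 adjusted over the list alone, mean -0.03, adjusted p = 0.0286, and adjusted p = 0.692 with an estimated correlation). The cholesterol call was lost without replicate 1 of siDNMT3A, siDNMT3B, siDNMT3L or 3A+3B or replicate 2 of siNTC-1, 3A+3L or 3B+3L (means from -0.04 to -0.03). The ribosomal call was lost without any of these arrays except those of siNTC-1 and siDNMT3A (means from -0.03 to -0.02), and with only the groups compared (adjusted p = 0.0532). With the nearer controls neither the cholesterol (0.01, adjusted p = 0.753) nor the ribosomal list (-0.03, adjusted p = 0.0751) was called, and with siNTC-1 alone the ribosomal list was not (adjusted p = 0.0618). The average effect called 2721 genes, 5 of them by at least 1.5-fold, and 1249 with the nearer controls. With DNMT3L siRNA, the epithelial genes EPCAM (0.51 ± 0.05) and CDH3 (0.47 ± 0.04) were higher, with PYY (0.46 ± 0.06), CYP26A1 (0.46 ± 0.05) and ZSCAN10 (0.46 ± 0.04). PON2 (-0.75 ± 0.04), MEIS2 (-0.72 ± 0.04), SHISA3 (-0.64 ± 0.07), TDG (-0.55 ± 0.07) and PXMP2 (-0.55 ± 0.04) were lower. Pluripotency genes rose in 10 of 23 members and none fell (10 and 0 adjusted over the list alone, mean 0.08, adjusted p = 0.00042, and adjusted p = 0.0563 with an estimated correlation), with DPPA3 at 0.34 ± 0.02 (0.18 with the nearer controls) and DPPA4 at 0.32 ± 0.02. Stress-response genes were lower with it (14 of 23 and 2 higher, 15 and 2 adjusted over the list alone, mean -0.22, adjusted p = 3.4e-11, and adjusted p = 0.0249 with an estimated correlation). The average effect called 2933 genes, 10 of them by at least 1.5-fold, and 3276 with the nearer controls.

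Interactions tested whether an siRNA acted differently in the presence of another. DNMT1 and DNMT3B mRNA fell less in every combination than after their siRNA alone. DNMT1 was at 39.3% of control in siDNMT1 and 56.7% in siD1+3A+3B, and DNMT3B at 56.0% in siDNMT3B and 89.3% in 3A+3B+3L. A weaker depletion therefore cannot be told apart from a different action. DNMT1 x DNMT3A called 2104 genes, with EGR1 highest (0.85 ± 0.08, and 0.55 with the nearer controls) and LINC01356 lowest (-1.21 ± 0.20). DNMT1 x DNMT3B called 5062 genes, led by CHAC1 (2.33 ± 0.12), PCK2 (1.81 ± 0.08) and INHBE (1.71 ± 0.12), and DUSP6 was lowest (-1.64 ± 0.14). With the nearer controls DUSP6 was at -1.48. CHAC1 (-0.32, adjusted p = 0.173), PCK2 (-0.19, 0.274) and INHBE (-0.52, 0.0347) turned, and only INHBE was called. DNMT3A x DNMT3B called 2099 genes, with AAMP at 0.96 ± 0.07 and TXNIP at -1.64 ± 0.07, which were at 0.42 and -0.70 with the nearer controls. DNMT3A x DNMT3L called 4178 genes, among them INHBE (-2.83 ± 0.12), DDIT4 (-2.79 ± 0.08) and CHAC1 (-2.61 ± 0.12), which were at -2.09, -2.13 and -1.72 with the nearer controls. DNMT3B x DNMT3L called 6721 genes, with CHAC1 at 2.41 ± 0.12 and SNORD14E at -1.58 ± 0.12, which were at -0.23 and 0.33 with the nearer controls. The counts with the nearer controls were 980, 2288, 403, 2218 and 1881 in the order given. Of the genes called both ways, 378 had opposite directions against 795 with the same in DNMT1 x DNMT3B, and 194 against 1057 in DNMT3B x DNMT3L.

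Some lists that were not called against both controls were called with the nearer control. Stress-response genes in siD1+3A+3B were lower in 18 of 23 members and higher in 2 (18 and 2 adjusted over the list alone, mean -0.52, adjusted p = 2.6e-13, and adjusted p = 0.0105 with an estimated correlation), whereas their mean was 0.03 against both controls and 0.59 against siNTC-1 (adjusted p = 1.9e-07). That list alone kept its call with an estimated correlation among those given here. Cholesterol synthesis genes were higher in siDNMT3A (10 of 16, 12 adjusted over the list alone, mean 0.27, adjusted p = 2.1e-07) and 3A+3B (9 of 16, 10 adjusted over the list alone, mean 0.23, adjusted p = 1.8e-07). They were higher in the average effects of DNMT3A (14 of 16, 15 adjusted over the list alone, mean 0.32, adjusted p = 3.6e-11) and DNMT3L (6 of 16, 7 adjusted over the list alone, mean 0.08, adjusted p = 0.00108). With an estimated correlation the adjusted p of these 4 was 0.112, 0.111, 0.052 and 0.375. With siNTC-1 alone the list was lower in siDNMT3A (-0.17, adjusted p = 0.0264) and 3A+3B (-0.20, adjusted p = 0.0130), and its means in the average effects were -0.008 and -0.03 (adjusted p = 0.918 and 0.411). DNA replication genes were lower in siDNMT1 (21 of 28, 23 adjusted over the list alone, mean -0.23, adjusted p = 2.3e-09), siDNMT3B (11 of 28, 15 adjusted over the list alone, mean -0.155, adjusted p = 0.00108) and siDNMT3L (15 of 28, 17 adjusted over the list alone, mean -0.16, adjusted p = 4.4e-05), each with 1 member higher. They were higher in the average effect of DNMT3A (14 of 28 and 2 lower, 15 and 2 adjusted over the list alone, mean 0.14, adjusted p = 2.1e-05). With an estimated correlation the adjusted p was 0.052, 0.328, 0.192 and 0.172. With siNTC-2 alone the direction was opposite in siDNMT1, siDNMT3B and siDNMT3L (means 0.103, 0.175 and 0.167, adjusted p = 0.0748, 0.0146 and 0.0101), and so it was with siNTC-1 alone in the average effect of DNMT3A (-0.104, adjusted p = 0.00931). Mitosis genes were higher in siD1+3B, siD1+3A+3B and 3A+3B+3L (means 0.14, 0.10 and 0.105, adjusted p = 0.00096, 0.00190 and 0.00205, and adjusted p = 0.173, 0.209 and 0.216 with an estimated correlation) and in the average effects of DNMT1 and DNMT3A (0.05 and 0.07, adjusted p = 0.0126 and 0.0309, and 0.334 and 0.387 with an estimated correlation). Pluripotency genes were higher in 3B+3L (9 of 23, 9 adjusted over the list alone, mean 0.11, adjusted p = 0.00131, and adjusted p = 0.0641 with an estimated correlation). Metallothioneins in siDNMT3A (mean 0.17, adjusted p = 0.0243), hypoxia genes in siDNMT3L (0.15, adjusted p = 0.00200) and X-linked cancer-testis genes in the average effect of DNMT1 (0.09, adjusted p = 0.0452) were higher, and germline genes in 3A+3B lower (-0.11, adjusted p = 0.0474), with adjusted p = 0.107, 0.387, 0.111 and 0.232 with an estimated correlation. With siNTC-2 alone neither the last list (adjusted p = 0.0560) nor the cancer-testis list (adjusted p = 0.0536) was called. Of the lists for RNA quality, respiratory chain genes were higher in siD1+3A, 3A+3L and the average effect of DNMT3A (means 0.17, 0.13 and 0.11, adjusted p = 0.00207, 0.0198 and 0.00415) and lower in siDNMT3L (-0.10, adjusted p = 0.0309), and ribosomal protein genes were higher in siD1+3A (0.11, adjusted p = 0.0256). With an estimated correlation the adjusted p of these 5 was 0.451, 0.587, 0.470, 0.623 and 0.623. The mean of respiratory chain genes turned in siD1+3A (-0.048) and 3A+3L (-0.08) with siNTC-1 alone and in siDNMT3L (0.116) with siNTC-2 alone, and that of mitosis genes in siD1+3A+3B (-0.010) and 3A+3B+3L (-0.006) with siNTC-1 alone, none of them called (lowest adjusted p = 0.532). In the average effect of DNMT3A neither the respiratory chain nor the mitosis list was called with siNTC-1 alone (adjusted p = 0.944 and 0.912) or siNTC-2 alone (0.730 and 0.754).

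The remaining 12 of the 24 lists were called in none of the 15 comparisons, with either set of controls. The lowest adjusted p of camera was 0.527 for neuroectoderm (mean -0.10 in siDNMT1), 0.543 for mesendoderm and mesoderm (0.05 in siD1+3B), 0.413 for fibroblast and mesenchyme (0.06 in 3A+3L) and 0.527 for HOX genes (-0.05 in siDNMT3A). It was 0.359 for endoderm (0.06), 0.108 for p53 targets (-0.10) and 0.284 for blood cell genes (0.07) in the average effect of DNMT1 depletion. In that of DNMT3L depletion it was 0.332 for trophoblast (-0.05) and 0.190 for imprinted genes (-0.04). For interferon response genes (-0.10) and small RNA machinery (0.06) it was 0.456 and 0.407 in siDNMT3B, and for chromatin repressors and DNA demethylation (0.06) it was 0.513 in siD1+3A.

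Finally, the single depletions were compared with each other across genes, which are not independent replicates. The differences from control of siDNMT3B and siDNMT3L correlated at 0.773 (covariance 0.0442), those of siDNMT1 and siDNMT3L at 0.706 (0.0379) and those of siDNMT1 and siDNMT3B at 0.656 (0.0368). Unchanged groups simulated against the same 4 controls gave correlations of 0.331 to 0.337 and covariances of 0.00195 to 0.00199. The simulation held the spread of duplicates only and no difference between siNTC-1 and siNTC-2. It is therefore no measure of what depletions on the same side share through the controls. siDNMT3A correlated with siDNMT1, siDNMT3B and siDNMT3L at -0.123, -0.133 and -0.195, but the sign depended on the control: with the nearer control of each they were 0.126, 0.079 and 0.097 (simulated -0.003, 0 and 0), and with the other control of each -0.654, -0.642 and -0.685. With siNTC-1 as control of the first depletion and siNTC-2, the control on the other side, of the second, the first 3 correlations were 0.129, 0.064 and 0.088. With siNTC-1 for both they were 0.717, 0.616 and 0.586, against simulated values of 0.502, 0.499 and 0.502, and the covariances exceeded the simulated ones by 0.0283, 0.0215 and 0.0232. siDNMT3B and siDNMT3L shared 1738 higher and 2356 lower genes, against 422.2 and 680.7 for independent lists. With siNTC-1 alone as control they shared 1056 and 1005, against 203 and 225.4. Part of these overlaps may come from the shared controls.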

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

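The tests of explanations, the other splits, the block by array set and the comparison of unnamed transcript clusters were chosen after the results were seen, and the interactions before. A weaker depletion in combinations, as seen for DNMT1 and DNMT3B mRNA, cannot be told apart from an interaction. Interactions called 2104 genes for DNMT1 x DNMT3A, 5062 for DNMT1 x DNMT3B, 2099 for DNMT3A x DNMT3B, 4178 for DNMT3A x DNMT3L and 6721 for DNMT3B x DNMT3L in limma's model of 13 groups, and 980, 2288, 403, 2218 and 1881 with the set as a block. Every division of the 8 cells of a factorial (control and 7 depletions, with duplicates kept together) into 4 and 4 was counted in the model of 13 groups. Of these 35 splits, 31, 12, 31, 17 and 8 called as many genes as the real interaction, and the highest of the others called 8818 for the first 2 interactions and 9639 for the last 3. Even the lowest called 1531 and 1472. The other splits hold effects of the siRNAs and the difference between the array sets, so these counts decide nothing about chance.

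The same count was made for the average effects, which called 4041 genes for DNMT1, 8332 for DNMT3A, 2721 for DNMT3B and 2933 for DNMT3L. As many were called by 17, 4, 24 and 23 of 35 splits, and the highest other split called 8818 for DNMT1 and 9639 for the others, which for the same reason decides nothing about chance. The split with 8818 genes set control, siDNMT1, siDNMT3B and siD1+3B apart from the rest and that with 9639 set control, siDNMT3B, siDNMT3L and 3A+3B+3L apart. Both were as close to the array sets as any of the 35 (correlation 0.729), as was the real split for DNMT3A, which called 4099 genes with the set as a block. Splits of single arrays were counted in a simpler model of 2 groups of arrays, 100 for each effect with the real one included. Only the real split reached its own count for DNMT1 (212 genes), DNMT3A (2037) and DNMT3L (35), where the highest other called 0, and 3 splits did so for DNMT3B (1 gene, highest other 1953). For each interaction limma called 0 genes in that model (915, 1474, 824, 1309 and 2745 at an unadjusted p under 0.05), which all 100 splits reached. These splits were drawn without regard to duplicates, which the real one keeps together, so they do not settle chance for the counts of the 13-group model.

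Among the 12083 transcript clusters without a gene symbol, which no comparison of genes used, 252 changed in siDNMT1 against siNTC-1 and 82 of them changed by at least 1.5-fold, 51 higher and 31 lower. Between siNTC-2 and siNTC-1, 1258 such clusters differed by at least 1.5-fold.

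The division of the arrays into 2 sets was weighed first. On a line through the controls, with siNTC-1 at 0 and siNTC-2 at 1, siDNMT3L, siDNMT1 and siDNMT3B lay at 0.127, 0.164 and 0.174 and the others from 0.633 to 0.982. The gap of 0.459 argues against the control siRNAs alone as the cause only if no depletion group received them, which the labels do not state. It was measured on arrays already seen to divide, so it restates that division. The 1633 genes that differed by at least 1.5-fold between the controls argue against DNMT depletion alone. Separate cultures or array batches remain open: the labels hold 0 fields that name a batch, and this cannot be told apart from a difference between the siRNAs used in the groups.

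The lower stress-response list in some depletions was weighed next. The number of siRNAs as the only cause is argued against in the DNMT1 combinations by siD1+3A+3B, whose mean lay 0.333 above that of siD1+3A and siD1+3B, and in the DNMT3 combinations by a range of 0.833 among 3A+3B, 3A+3L and 3B+3L, although 3A+3B+3L (-0.423) lay below each of them (0.377, -0.294 and 0.539). A high state of siNTC-2 alone is argued against for 3A+3L, which lay below siDNMT3A (difference -0.624) with no control involved, but stays open for siDNMT1, siDNMT3B and siDNMT3L, whose means of -0.834, -0.689 and -0.670 were -0.278, -0.132 and -0.114 against siNTC-1. A culture state that differed between the groups remains open, because the controls differed by 1.113 without any depletion. A biological effect of the depletions also stays open, as untested.

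The rise of germline and meiosis genes with DNMT1 siRNA was weighed last. The choice of control is argued against for siDNMT1 by the lower of its means against the 2 controls, 0.184, but stays open for siD1+3A, siD1+3B and siD1+3A+3B, whose means were 0.123, 0.124 and 0.073 against siNTC-1 and 0.056, 0.056 and 0.006 against siNTC-2. The stress-response state is argued against by 3A+3L and 3A+3B+3L, where without DNMT1 siRNA the stress-response means were -0.850 and -0.979 against siNTC-2 and the germline means against the same control -0.121 and -0.137. Culture or batch was not excluded: the list was also higher in 3 pairs within a set of arrays (means 0.251, 0.117 and 0.112, together 0.16 with adjusted p = 1.7e-06, and adjusted p = 0.0138, 0.206, 0.0935 and together 0.00843 with an estimated correlation). Loss of DNMT1-dependent silencing is a hypothesis, and an off-target action of the siRNA may contribute as well: neither was tested, and the lower mean of 0.184 does not separate them.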

How the results depend on the processing

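The set block and within-set pairs were chosen after the data were examined, the other alternatives before. The cause of each change below was not tested, except where an alternative uses fewer arrays. Quantile normalization, the variance prior, array weights and all clusters kept every count within 1.5 times, and so did the dim-gene filter. Named genes kept direction and call in all 214 results with quantile normalization, the variance prior and array weights and in the 198 that could be tested without dim genes. List calls changed in some cases: the dim-gene filter ended 12 and added 1, quantile normalization ended 5 and added 1, the trended prior ended 2 and added 4, and array weights ended 1. With siNTC-1 alone as control, the counts were 3653 in siDNMT1, 8379 in siDNMT3A, 3532 in siDNMT3L, 7660 in siD1+3A, 7320 in siD1+3A+3B, 8142 in 3A+3B and 7216 in 3A+3B+3L, 4914 for the average effect of DNMT3B, and 4656, 2895 and 4668 for DNMT1 x DNMT3A, DNMT1 x DNMT3B and DNMT3A x DNMT3B. With siNTC-2 alone they were 2911 in siDNMT3A, 2319 in 3A+3B, 1860 in 3B+3L, 1249 for DNMT3B, and 980, 403 and 2218 for DNMT1 x DNMT3A, DNMT3A x DNMT3B and DNMT3A x DNMT3L. With the array set as a block they were 3653 in siDNMT1, 2911 in siDNMT3A, 3532 in siDNMT3L, 2319 in 3A+3B, 1860 in 3B+3L, 3298, 3228 and 2908 against siDNMT1, 4099 for DNMT3A, 1249 for DNMT3B, and 980, 2288, 403, 2218 and 1881 for the interactions. Within-set pairs gave 3351 for DNMT3A. With only the groups of a comparison, which leaves fewer arrays to estimate the spread, they were 3362 in siDNMT1, 3469 in siDNMT3A, 4324 in siDNMT3B, 3930 in siDNMT3L, 3324 in siD1+3B, 2539 in siD1+3A+3B, 2925 in 3A+3L and 2985 in 3A+3B+3L.

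Leaving out each array in turn assumes that a lone array varies like the other groups. The counts then ranged from 3142 (without siDNMT3A replicate 1) to 5452 in siDNMT3A, 2962 (without siD1+3A replicate 2) to 4989 in siD1+3A, 3259 (without siD1+3B replicate 1) to 4927 in siD1+3B, 2723 (without siD1+3A+3B replicate 1) to 4416 in siD1+3A+3B, 2917 (without 3A+3B replicate 2) to 4868 in 3A+3B, 3338 (without 3A+3L replicate 2) to 4904 in 3A+3L and 2673 (without 3A+3B+3L replicate 1) to 4559 in 3A+3B+3L. Leaving out the other replicate also moved the count by over 1.5 times in siD1+3A (3163), siD1+3B (3290), siD1+3A+3B (2838), 3A+3B (3044) and 3A+3B+3L (2707). Other counts stayed within 1.5 times. No named gene or list changed sign. Of the gene calls 10 were lost, all of DNMT3B or DNMT3L as targets, and of the list calls 23 were lost and 13 gained.

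Of the list calls, 14 held with an estimated correlation and fry made 176. Lists that turned with siNTC-2 alone and with the set block were stress response in siDNMT3A (-0.226), 3A+3B (-0.179), 3B+3L (-0.017) and the average effect of DNMT3B (-0.029), DNA replication in siDNMT3A (0.021), siD1+3A (0.074), siD1+3B (0.073), siD1+3A+3B (0.010) and 3A+3L (0.057), and cholesterol synthesis in 3B+3L (0.001) and the average effect of DNMT3B (0.011). So did stress response in siD1+3A+3B (-0.524). DNA replication in siDNMT3B (-0.155) and siDNMT3L (-0.163) and the respiratory chain in siDNMT3L (-0.098) turned with siNTC-1 alone and the block. In the average effect of DNMT3A stress response (-0.493), mitosis (0.067), DNA replication (0.143) and the respiratory chain (0.114) turned with the block. With siNTC-1 alone stress response turned in siD1+3A (0.335), siD1+3B (0.176), 3A+3L (0.263) and 3A+3B+3L (0.134), and cholesterol synthesis in siD1+3A+3B (-0.030), siDNMT3A (-0.168) and 3A+3B (-0.203). Genes that turned were CHAC1 (-0.381), DDIT4 (-0.187) and MCM7 (0.101) in siDNMT3A with siNTC-2 alone and the block, ALDH1L2 in siD1+3A with siNTC-1 alone (0.066), and with the block CHAC1 (-0.321), PCK2 (-0.187) and INHBE (-0.517) in DNMT1 x DNMT3B and CHAC1 (-0.234) and SNORD14E (0.334) in DNMT3B x DNMT3L. With the block 183 gene results kept direction and call, 17 lost the call and 8 turned, and of the list results 37 kept both, 10 lost the call, 18 gained one and 19 turned.

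Correlations of siDNMT1 and siDNMT3A, siDNMT1 and siDNMT3B, siDNMT1 and siDNMT3L, siDNMT3A and siDNMT3B, siDNMT3A and siDNMT3L, and siDNMT3B and siDNMT3L were 0.126, 0.586, 0.616, 0.079, 0.097 and 0.717 with the block. With siNTC-1 for the first and siNTC-2 for the second they were 0.126, 0.088, 0.064, -0.642, -0.685 and 0.129, and exchanged -0.654, 0.069, 0.135, 0.079, 0.097 and 0.226. Without dim genes the first 3 were -0.169, 0.714 and 0.773 and the last 0.796.

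Samples share replicate numbers only: correlations of deviations over 78 pairs of groups ran from -0.258 to 0.191 (median -0.002, 9 over 0.1). With the replicate block, 5593 genes changed in siDNMT1, and no count, named gene or list changed its call.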

Other observations

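The gene families and within-set comparisons of this part, and their tests, were chosen after the data were examined. Small nucleolar RNA genes, whose products guide modification of ribosomal RNA, were lower in siNTC-2 than in siNTC-1 (mean -0.448, 102 of 176 lower and 16 higher). Against the nearer control they were higher in 7 of the 8 depletions on the side of siNTC-2: 87 of 176 members were higher and 4 lower in 3A+3B+3L (mean 0.275, adjusted p = 7.4e-18, and adjusted p = 9.4e-07 with an estimated correlation), and 84 and 3 in siD1+3B (mean 0.266). In 3B+3L they were not called (mean 0.039, adjusted p = 0.157). In siDNMT3B they were lower than in siNTC-1 (40 of 176 lower and 7 higher, mean -0.130, adjusted p = 0.000345, and adjusted p = 0.00143 with an estimated correlation, -0.12 after quantile normalization), but the mean against both controls was 0.094. Against the mean of both controls the means in 3A+3B+3L and siD1+3B were 0.051 and 0.042, and in siDNMT3A, 3A+3B and siD1+3A+3B they turned to -0.095, -0.130 and -0.040. After quantile normalization the means against the nearer control kept their sign in these 7 depletions (from 0.104 to 0.274). Replication-dependent histone genes were higher in siD1+3A, siD1+3B and siD1+3A+3B with both readings (means 0.355, 0.383 and 0.281 against both controls, 0.193, 0.221 and 0.119 against siNTC-2, and 0.190, 0.220 and 0.120 against siNTC-2 after quantile normalization). Of these the list passed the threshold with an estimated correlation in siD1+3B alone (adjusted p = 0.0284). In siDNMT1 the means were 0.021 against both controls and 0.183 against siNTC-1 (adjusted p = 0.00135, and adjusted p = 0.0855 with an estimated correlation). Without DNMT1 siRNA they were also higher in siDNMT3B against siNTC-1 (21 of 57 higher and 1 lower, mean 0.167, adjusted p = 0.000624, and adjusted p = 0.0700 with an estimated correlation, 0.179 after quantile normalization), where the mean against both controls was 0.005 and -0.002 after quantile normalization. In the average effect of DNMT3B they were higher with both readings (means 0.107 and, with the nearer controls, 0.067, there with adjusted p = 3.3e-06, and adjusted p = 0.0165 with an estimated correlation). Near-identical histone genes can share probes, so the members are not separate measurements. Olfactory receptor genes (341), which are not expressed in most cells, passed the threshold in none of 15 comparisons with the nearer controls (camera, lowest adjusted p = 0.144). Zinc finger genes (494) were called in 6 of them, in siDNMT1, siDNMT3B, siDNMT3L, 3B+3L and the average effects of DNMT1 and DNMT3A, and in none with an estimated correlation (lowest adjusted p = 0.0855).

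Depletions that differ by an siRNA were compared within a set of arrays, without a control where possible. DNMT1 siRNA gave 3653 changed genes in siDNMT1 minus siNTC-1, 1771 in siD1+3A minus siDNMT3A and 587 in siD1+3A+3B minus 3A+3B. Across these 3 pairs 59 genes were called higher each time, led by H3C11, MAEL, GTSF1, H1-5 and HORMAD1, and 115 lower, led by HHIP, DNMT1, INHBE, PCK2 and TRIB3. DNMT3L siRNA gave 119 genes higher and 220 lower in each of 3 pairs, with DUSP6, RASL11B and GUCY2C among the first and HHIP, DDIT4 and SESN2 among the second. DNMT3A siRNA gave 15 and 31. DNMT3B siRNA gave 4465 changed genes in siDNMT3B minus siNTC-1 but 17 in 3A+3B minus siDNMT3A, 18 in 3A+3B+3L minus 3A+3L and 105 in siD1+3A+3B minus siD1+3A, and limma called 0 genes in the same direction in all 4 pairs (6 higher and 20 lower at an unadjusted p under 0.05 in each). DNMT3B mRNA was at 50.3%, 67.1%, 82.0% and 75.4% in those pairs, and its fall was not past the threshold in 3A+3B+3L minus 3A+3L (adjusted p = 0.106). Stress-response genes were lower with DNMT1 siRNA in its 3 pairs (means -0.278, -0.551 and -0.345) and with DNMT3L siRNA in its 3 pairs (-0.114, -0.624 and -0.800), in each of which camera called the list. With an estimated correlation the siDNMT1 and siDNMT3L pairs with siNTC-1 were not called (adjusted p = 0.0924 and 0.361). With DNMT3A siRNA the list was lower in siDNMT3A minus siNTC-2 (-0.226, adjusted p = 5.4e-06, and adjusted p = 0.0941 with an estimated correlation) and 3A+3B+3L minus 3B+3L (-0.962) but higher in siD1+3A+3B minus siD1+3B (0.413, adjusted p = 2.5e-22, and adjusted p = 0.00231 with an estimated correlation).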
